A study of Homo sapiens with 8 samples.

How the data were processed

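Gene expression was measured on 8 Illumina HumanHT-12 v4 BeadChip arrays, with 47323 probes each. The RNA came from WERI RB1 cells, a human retinoblastoma line grown in suspension. Per the labels, 4 arrays carried RNA of cells transfected with FASN siRNA and collected after 48 hours, and 4 carried RNA of untransfected cells. Each group held 2 arrays of replicate 1 (transfection line P-5) and 2 arrays of replicate 2 (transfection line P-6). Per the labels' protocols, RNA was extracted with Trizol, cleaned up and treated with DNase on RNeasy columns, and biotinylated cRNA was made with the Ambion MessageAmp kit.

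The authors deposited a table that is not normalized, exported from GenomeStudio 1.8.0 per the file headers, with a mean bead intensity for every probe on every array. Beside each intensity, the deposited table holds a detection value, a fraction from 0 to 1 that equals 1 minus the detection p-value; it was turned back into a p-value. The authors also deposited log2 values in a series matrix. Its scale and centring were worked out from the intensities: 99.98% of its differences between arrays matched log2 intensity minus the array's median within 0.011. Every probe also had a constant subtracted. That constant lay near the probe's median over the 8 arrays, at a median absolute difference of 0.026. This exceeds 0.011, so its exact origin stays unknown. The median of its columns lay between -0.01 and 0.01. These values served as an alternative. No genome build was given in the sources used here, so no coordinates are printed.

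Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, using the detection p-values and an offset of 16, and are on a log2 scale. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, 22857 of 47323. Arrays that shared a group, line and replicate label were averaged, because nothing in the labels says that they came from separate cultures. This left 2 samples per group. The limma p-values for single probes therefore rest on the spread between the lines within a group, moderated by that of the other probes. Of 5.93 total degrees of freedom, 3.93 came from the other probes. FASN siRNA was compared with control by limma (lmFit and eBayes) with Benjamini-Hochberg adjustment, and every adjusted p printed for a gene is from that fit unless another is named. The labels pair the groups by line. The deviations of same-line samples from their group means correlated at 0.24 across probes. With 2 samples per group, both pairs give the same value, so this is a single estimate. The fit without the pairing was fixed as the reported one and the fit with the line as a block as an alternative.

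Symbols were brought up to date through the RefSeq gene table of GRCh38.p14. Of the tested probes, 15290 already carried a current symbol, 2642 were renamed through a synonym, 1287 through the gene ID inside a LOC symbol, and 3638 kept the name in the file. The step through gene IDs was added after the data had been looked at. Y-linked probes and XIST are not shown, which left 22845 probes. Where a group had no array with a probe above background (detection p under 0.05), a lower bound replaces the fold: the bright group's mean was set against the dim group's mean after each dim value was raised to the array's lowest detected value.

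The genes named follow a rule set before the data were examined. It takes FASN; the 10 genes highest and the 10 lowest in the siRNA samples among those that pass the test and move the same way in both lines, or, where too few pass, those with the smallest unadjusted p; and the 3 members with the smallest unadjusted p of each of 9 lists and of every other list called. Of the genes this rule names, 2 are not reported here. Other genes are said to have been chosen after their values were seen. There were 31 gene lists, also fixed before the data were examined. They cover lipid metabolism, the cell cycle, stress and signalling pathways, energy metabolism, ribosomes, and markers of retinal and other cell types. Each list was tested with camera at a preset inter-gene correlation of 0.01 on 17660 genes, taking the tested probe with the highest mean for each gene, and adjusted over the 31 lists. With the preset correlation, camera sets a list against the other genes, so its p-value does not measure how the list varies between samples. Camera with an estimated correlation and fry were run as well. With an estimated correlation, camera is held to the residual degrees of freedom of the fit, which are few with 2 samples per group. A call lost there is therefore not by itself due to correlation. The median of each list was also placed among those of 10000 random lists of the same size matched on mean log2 value.

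On simulated data with the means and spread of these probes, the fit of FASN siRNA against control over 22857 probes recovered 44 of 50 probes changed 2-fold, and 50 of 50 at each of 4-fold, 8-fold and 16-fold. It called 20 of 22657 unchanged probes. The simulated noise was independent between probes and was drawn from the variances already moderated by the fit. In the data RNU1-5, 3.63-fold higher, had an adjusted p of 0.603 in limma. The simulated counts therefore do not show that changes of these sizes would be called here. In a second simulation camera called 1 list of 30 probes shifted by 0.25 and 0 of the other lists. Its probes were independent, whereas the estimated inter-gene correlation of the lists called in the data reached 0.252, so it does not test the preset correlation. The alternatives covered background correction, normalization, the series matrix values, the filter on dim probes, the offset, the treatment of duplicate arrays, the block, the prior variance, and leaving out each averaged sample. A block on the BeadChip was not run, since chip positions are not given in the sources used here. The number of arrays limits the precision.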

Results

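Fatty acid synthase, the enzyme encoded by FASN that builds palmitate from acetyl-CoA and malonyl-CoA, was targeted by siRNA in WERI RB1 retinoblastoma cells. Genome-wide transcript levels were measured 48 hours after transfection and set against those of untransfected cells. Each group held 2 samples, 1 from transfection line P-5 and 1 from P-6, and each sample was the average of 2 arrays. The mean bead intensity of an array ranged from 596 to 764 in control and from 538 to 613 in siRNA arrays. In P-6 it was 748 and 764 in control against 538 and 572 in siRNA arrays. Per array, 22404 to 22983 probes were above background. Arrays that shared a replicate label correlated at 0.996 to 0.997 across the tested probes, against 0.990 to 0.994 for arrays of the same group from the other line and 0.991 to 0.994 for arrays of the other group from the same line.

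FASN, the siRNA target, had a normalized log2 intensity of 12.95 ± 0.24 (SD, n = 2) in control cells and 12.50 ± 0.07 (SD, n = 2) in siRNA cells. The log2 fold change was -0.45 (SE 0.152), 1.37-fold lower, and the single FASN probe was lower in both lines, by -0.57 in P-5 and -0.33 in P-6. In the deposited intensities, the 4 control arrays lay between 8056 and 10287 and the 4 siRNA arrays between 4706 and 5827. These intensities are not normalized, and part of that gap goes with the lower mean intensity of siRNA arrays (538 to 613 against 596 to 764). The difference did not pass the test in limma (adjusted p = 0.603). Median centring in place of quantile normalization gave -0.67 (adjusted p = 0.434), with the median of all tested probes at -0.13.

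**Figure D1:**
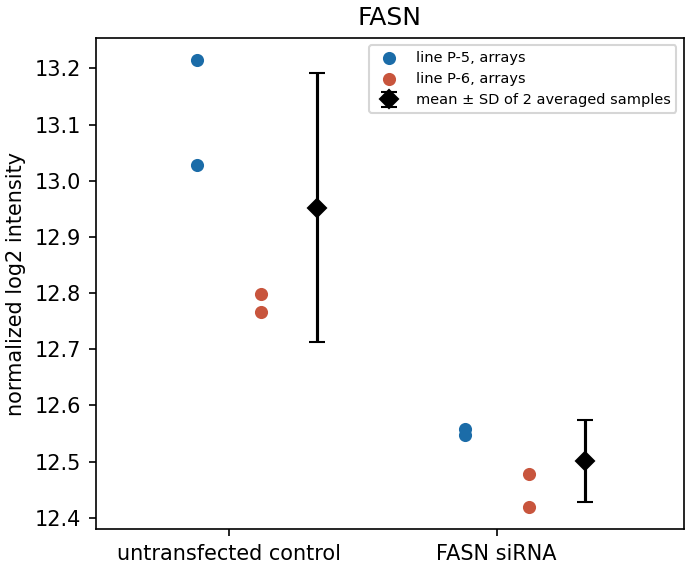
Normalized log2 intensity of the FASN probe (vertical axis) on each array of the untransfected and FASN siRNA groups, coloured by transfection line, with the mean ± SD of the 2 averaged samples per group. Means were 12.95 and 12.50, and each siRNA array lay below each control array.

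Which transcripts moved with FASN siRNA was asked over all tested probes. Of the 10 genes with the smallest unadjusted p among those higher in both lines, spliceosomal U1 small nuclear RNAs stood highest: RNU1-5 was 3.63-fold higher (log2 fold change 1.86, SE 0.287), RNU1-3 stood at 1.77 (SE 0.272) and RNU1-4 at 1.76 (SE 0.223). RNU1-3 was above background on 2 and RNU1-4 on 1 of the 4 control arrays, so their sizes rest on control values at background, and a second probe assigned to RNU1-4 stood at 0.12. Among protein-coding genes, ABCC5, an exporter of cyclic nucleotides, had a log2 fold change of 0.86 (SE 0.156; 1.00 at its other probe). The phosphoinositide kinase PIP5K1A stood at 0.84, PLEKHA6 at 0.82, and DPM3, a subunit of dolichol-phosphate mannose synthase, at 0.80 and 0.63 at 2 probes. The inhibin subunit INHBB stood at 0.80, the metallothionein MT2A at 0.72 and SRGAP3 at 0.67 (0.37 at its other probe). None of these passed (each adjusted p = 0.603).

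**Figure D2:**
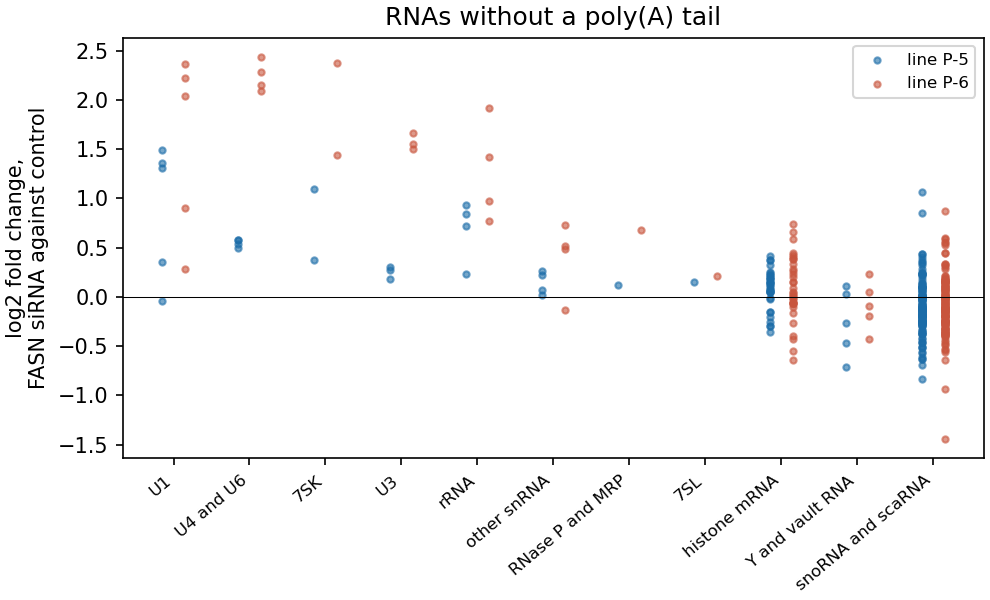
Log2 fold change of FASN siRNA against control (vertical axis) for each probe of 11 classes of RNA without a poly(A) tail, by transfection line. The medians of U1, U4 and U6, 7SK, U3 and ribosomal RNA ran from 0.91 to 1.76, with 1 U1 probe below 0 in P-5, and small nucleolar RNAs other than U3 have a median of -0.10.

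Of the genes with the smallest unadjusted p among those lower in both lines, CACNB2, a calcium channel subunit, stood lowest, at 7.29 ± 0.17 against 8.18 ± 0.12 (SD, n = 2), a log2 fold change of -0.90 (SE 0.14), with -0.48 at a second probe. GNGT1, the rod transducin gamma subunit, had -0.78, YJU2 -0.66, and GDF10 -0.64. YJU2 lay close to background in siRNA cells, at 5.18 where the lowest detected values of siRNA arrays were 5.01 to 5.07, so its size is uncertain. The neural adhesion gene CNTN1 had -0.62 and -0.48 at its probes, SCAF1 had -0.61, and LMO2, AFF2 and RSBN1L each had -0.60. None passed (each adjusted p = 0.603).

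No probe passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 928 higher and 936 lower of 22845 probes, where 1142 in all are expected by chance, and median centring turned that split to 340 higher and 2187 lower. The fit with the line as a block also called 0 probes, with 2844 at an unadjusted p under 0.05.

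Genes of fatty acid synthesis did not move together. Of 34 measured, 16 were higher and 18 lower, with a median log2 fold change of -0.03 (camera adjusted p = 0.958), and 0 passed over all genes or adjusted over the list alone. Beside FASN, the dehydratase HACD1 of long-chain elongation stood at -0.50 and MLXIPL, a glucose-responsive activator of lipogenic genes, at 0.41, with -0.09 at its second probe. Cholesterol synthesis had 17 of 25 genes higher, a median of 0.04 and an adjusted p of 0.281. MVK, mevalonate kinase, stood at -0.46, the sterol isomerase EBP at 0.27 and INSIG1, which retains SREBP in the endoplasmic reticulum, at 0.25 and -0.08 at 2 probes. Fatty acid oxidation had 22 of 27 genes higher with a median of 0.07 (adjusted p = 0.176), 0.14 in P-5 and 0.00 in P-6, and 10 of the 27 were higher in both lines. Without control replicate 2 the list was called (median 0.13, adjusted p = 0.0182, in a range of 0.0182 to 0.956 over its settings), and without control replicate 1 its median was 0.01. CPT1C, ETFB and ECHS1 had log2 fold changes of 0.27, 0.35 and 0.23, with 0.06 at the second ETFB probe. The lists of phospholipid and triglyceride synthesis, sphingolipid metabolism, and LXR and PPAR targets had medians of -0.02, -0.03 and -0.06, and none was called.

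In the list of ATF4 and the amino acid response, 24 of 32 genes were higher, 19 of them in both lines. The list's median was 0.13 (camera adjusted p = 0.0177, and 0.867 with an estimated correlation). Its estimated correlation was -0.03, below the preset 0.01, so the higher adjusted p does not come from a higher correlation in this list. The glutamine transporter SLC1A5 had a log2 fold change of 0.51, TRIB3 0.47 and ATF5 0.29. Of 28 targets of NRF2, the activator of antioxidant genes, 19 were higher, 15 of them in both lines. The list's median was 0.11 (camera adjusted p = 0.0343, and 0.867 with an estimated correlation). That median was 0.00 without FASN siRNA replicate 2, 0.06 without control replicate 1 and 0.23 without FASN siRNA replicate 1. Ferritin light chain, FTL, stood at 0.59, and at 0.40 at its other probe, the autophagy receptor SQSTM1 at 0.64 and sulfiredoxin, SRXN1, at 0.34. The autophagy and lysosome list had 22 of 34 genes higher, 16 of them in both lines. Its median was 0.06 (camera adjusted p = 0.0469, and 0.867 with an estimated correlation). That median lay within the 95% range of random lists matched on mean log2 value (-0.08 to 0.08). There the protease CTSB had 0.57 (0.31 at a second probe) and SQSTM1 0.64. With the line as a block, the call of the autophagy list was lost (adjusted p = 0.0707).

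The interferon response list had 35 of its 49 genes measured. Among those too dim to be tested were IFIT1, IFIT3, IFI44L, MX2, OAS2 and OASL. Of the 35 genes, 25 were higher, 23 of them in both lines. Their median was 0.21 (camera adjusted p = 0.0115, and 0.867 in camera with an estimated correlation). The exonuclease ISG20 had a log2 fold change of 0.60. DHX58, a RIG-I-like receptor, was above background only in siRNA cells and at least 1.15-fold higher there, while the chemokine CXCL10 was above background only in control cells and at least 1.15-fold higher there. Markers of pigment epithelium, vessels, stroma and immune cells were listed to look for other cell types, and 14 of the 30 were measured. Among those too dim to be tested were RPE65, TYR, CDH5, KDR, COL3A1, DCN and PTPRC. All 14 measured genes were higher, 11 of them in both lines. The median of the 14 was 0.25 (camera adjusted p = 0.00809, and 0.867 in camera with an estimated correlation). The lysosomal and macrophage gene CD68 stood at 0.62, and at 0.19 at its second probe, the melanogenic enzyme DCT at 0.39 and the monocyte receptor CD14 at 0.51. CD68 passed adjusted over the list alone (adjusted p = 0.0241), and 0 of the 14 passed over all genes.

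Both lists that were called lower concern growth. Of 32 ribosome biogenesis genes and MYC targets, 25 were lower, 21 of them in both lines, with a median of -0.18 (camera adjusted p = 0.0115; adjusted p = 0.867 with an estimated correlation), and of -0.09 without FASN siRNA replicate 2. The processome genes RRP9 and RRP12 had log2 fold changes of -0.50 and -0.40, whereas POLR1B, a core subunit of RNA polymerase I, stood at 0.47, and at 0.15 at a second probe. Of 45 G2/M and mitosis genes, 34 were lower, 22 of them in both lines. The list's median was -0.08 (camera adjusted p = 0.0343, and 0.876 with an estimated correlation), with -0.12 in P-5 and -0.03 in P-6. The kinesin KIF4A had -0.47, the spindle factor TPX2 -0.31 and the checkpoint kinase TTK -0.28.

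Fry called 0 of the 31 lists, with 3 at an unadjusted p under 0.05, and in these 7 lists 0 genes passed over all genes. With control replicate 1 left out only the G2/M list was called, and without FASN siRNA replicate 2 the G2/M list and oxidative phosphorylation were. The G2/M list itself was not called without FASN siRNA replicate 1 (adjusted p = 0.824, median 0.00) or without control replicate 2 (adjusted p = 0.416), in a range of 1.89e-06 to 0.824 over its settings. Under median centring the ATF4, NRF2 and autophagy lists were not called, with medians of -0.02, -0.01 and -0.09 against -0.13 for all tested probes, and the interferon list was not called among probes detected at p under 0.01 on all 8 arrays.

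**Figure D3:**
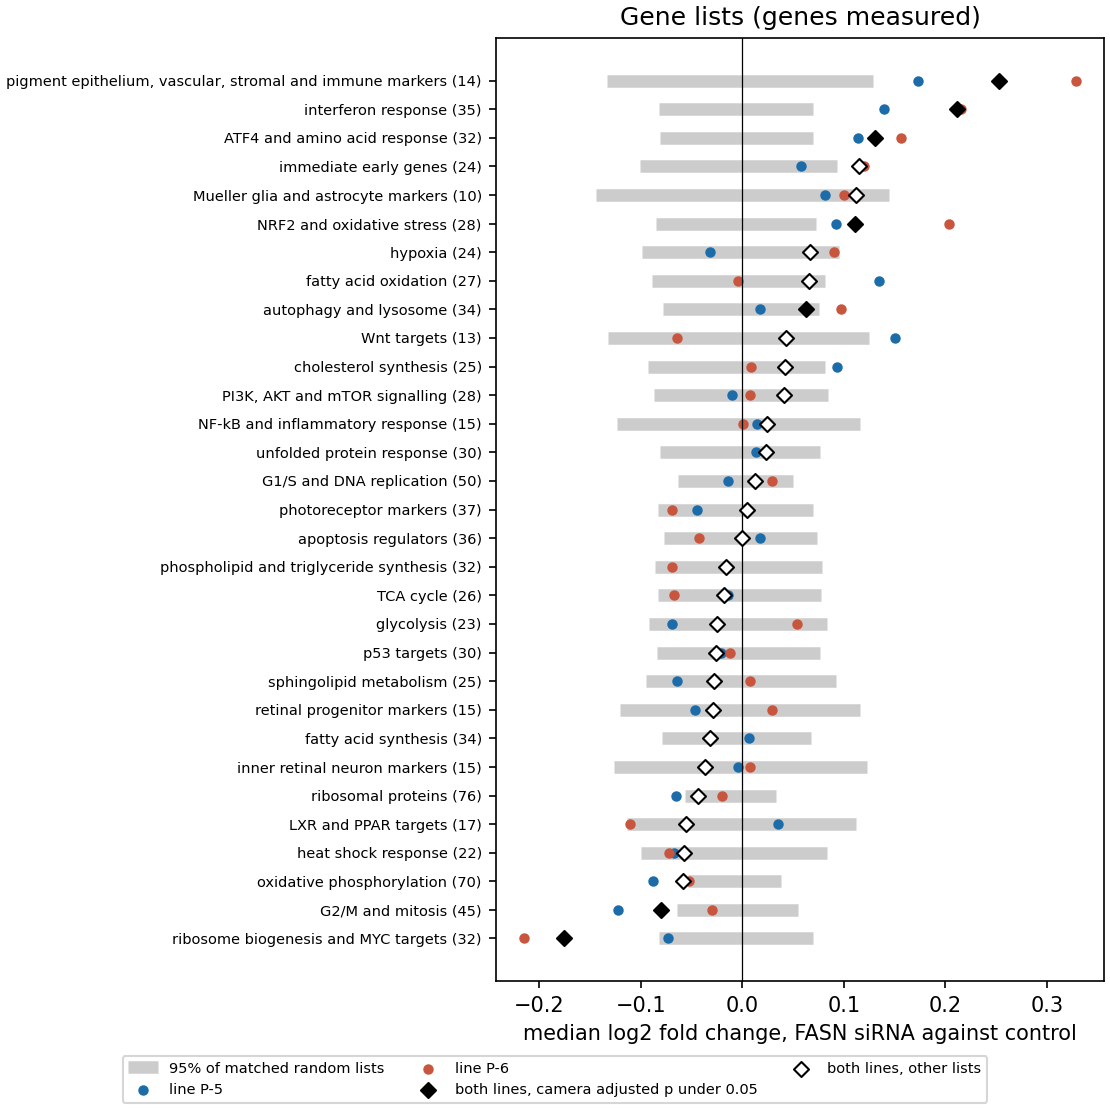
Median log2 fold change of FASN siRNA against control (horizontal axis) for each of the 31 gene lists, with the number of genes measured in brackets; diamonds are both lines together, coloured points are single lines, and grey bars span 95% of 10000 random lists matched on mean log2 value. The filled diamonds mark the 7 lists called by camera, from -0.18 for ribosome biogenesis to 0.25 for markers of other cell types.

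Genes of the cell cycle before mitosis and of cell death were mixed. The G1/S and DNA replication list had a median of 0.01 over 50 genes, with the replication factors GINS4 at 0.47, GINS1 at -0.67 and CDT1 at 0.39. GINS1 was above background on 3 of the 4 siRNA arrays, so its size rests in part on values at background. The p53 targets had a median of -0.03 over 30 genes, and TIGAR, FDXR and EDA2R stood at -0.45, -0.31 and -0.21. Over 36 apoptosis regulators the median was 0.00. HRK, a BH3-only activator of apoptosis, had 0.63 (SE 0.135), RIPK1 0.44 and BAD -0.31. The unfolded protein response list had a median of 0.02 over 30 genes, with CRELD2 at 0.31, PDIA6 at 0.31 and the sensor kinase EIF2AK3 at -0.33. None of these 4 lists was called, their camera adjusted p ran from 0.749 to 0.984, and none of the genes passed.

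The identity of the cells was followed through retinal markers. The photoreceptor list had 19 of 37 genes higher and a median of 0.00, and was not called (camera adjusted p = 0.246, in the lower direction). Retinal progenitor, inner retinal neuron and Müller glia markers had medians of -0.03, -0.04 and 0.11 and were not called. Oxidative phosphorylation had 48 of 70 genes lower and a median of -0.06 (adjusted p = 0.0753), and was called lower in 14 of 21 other settings (adjusted p from 6.29e-05 to 0.860). Ribosomal proteins and the TCA cycle, at medians of -0.04 and -0.02, and glycolysis and hypoxia, at -0.03 and 0.07, were not called. The same held for the heat shock response (-0.06), NF-kB and inflammatory response (0.02), Wnt targets (0.04) and PI3K, AKT and mTOR signalling (0.04). Immediate early genes had a median of 0.11 (adjusted p = 0.122). In that list 3 genes, named after their values were seen, passed adjusted over the list alone, each at an adjusted p of 0.0344: JUN at 0.64, KLF6 at 0.67 (0.71 at its other probe) and JUNB at -0.70.

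Whether both lines responded alike was described without a test, since each line holds 1 sample per group. Across probes, which are not independent replicates, the log2 fold changes of P-5 and P-6 correlated at 0.25 (Pearson; Spearman 0.297), and 61.2% of probes had the same sign. The SD of the log2 fold changes was 0.25 in P-5 and 0.30 in P-6. In both lines and the same direction, 102 probes were at least 1.5-fold higher and 20 at least 1.5-fold lower, while 57 were at least 1.5-fold apart from control in opposite directions.

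**Figure D4:**
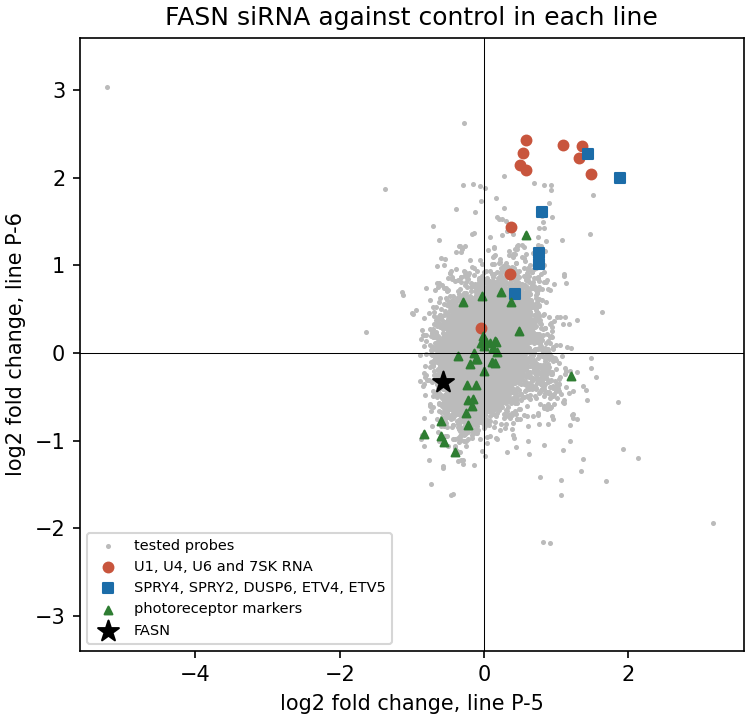
Log2 fold change of FASN siRNA against control in line P-5 (horizontal axis) and line P-6 (vertical axis) for each tested probe, with FASN and 3 groups of genes marked. FASN lies at -0.57 and -0.33, and the correlation across probes was 0.25.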

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

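The tests of array scaling and of the 18S and 28S ribosomal RNA probes were chosen after the results were seen.

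Of the genes named by the rule on unadjusted p, U1 small nuclear RNAs stood highest, with a median log2 fold change of 1.76 over 5 probes, 4 of them higher in both lines; 4 of the 5 were not above background on every control array. U4 and U6 (median 1.37), 7SK (1.32) and U3 (0.91) stood high too, each more so in line P-6, where U4 and U6 had a median of 2.22 against 0.56 in P-5. Scaling is argued against, since the lowest U1 median over the normalizations run was 0.98. A carry-over of all RNA without a poly(A) tail alike into labelling is argued against by 198 probes of that kind other than U1 and ribosomal RNA. Their median was -0.0694 (95% bootstrap interval -0.09 to -0.01), with medians of -0.10 for small nucleolar RNAs other than U3, -0.11 for Y and vault RNAs and 0.08 for histone mRNAs. The small nucleolar class (144 probes) and histone mRNAs (34) set that median. The single 7SL probe stood at 0.18. Its control mean of 14.22 lay near the top of the intensity scale, where a rise may be compressed. Other small nuclear RNAs and RNase P RNA stood at 0.27 and 0.40. A carry-over that differs between classes is therefore not excluded. A carry-over limited to abundant structural RNAs stays open: the 18S and 28S ribosomal RNA probes had a median of 1.13, and it could account for the pattern as well as any change in these RNAs in the cells. The 18S and 28S probes also differed between the lines among control samples, with SDs from 0.70 to 0.97 (n = 2).

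The interferon response list was higher in the siRNA samples. Its median of 0.21 lay at percentile 100 of random lists matched on mean log2 value, so a trend of fold change with brightness is argued against. The median was 0.10 without control replicate 1, 0.12 without FASN siRNA replicate 2 and 0.05 without a filter on detection. Lipofection and loss of FASN cannot be told apart here, because 0 of the control arrays came from transfected cells. Double-stranded RNA or the lipid reagent could raise such genes without any part of FASN, and the same holds for every other difference between the groups.

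Of 30 listed markers of pigment epithelium, vessels, stroma and immune cells, 14 were measured and all 14 were higher, 11 of them in both lines. The median of the 14 lay at percentile 99.97 of matched random lists, against a trend with brightness. The median of 0.25 became 0.10 without control replicate 1, 0.09 without FASN siRNA replicate 2, 0.44 without control replicate 2, 0.49 without FASN siRNA replicate 1 and 0.06 without a filter on detection. For 1 of 4 cell types, leukocytes, at least 3 of 5 abundant markers were detected on all siRNA arrays and higher in both lines: CD14 (0.51), HLA-DRA (0.20), CD74 (0.14) and AIF1 (0.13), while PTPRC was detected on 0 arrays. The rule set no minimum size: HLA-DRA stood at 0.04 in P-5 and 0.36 in P-6, and CD74 lay close to background in control cells, at 5.27. These 4 were also members of the list and were detected on all 4 control arrays. Fibroblast, endothelial and pigment epithelial markers met the rule for 0, 2 and 2 of 5 genes. Cells of another type stay open as a candidate explanation, as does a change in the retinoblastoma cells themselves.

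With all 8 arrays counted as samples, limma called 829 probes. Splitting the arrays by line called 524, and crossing the lines 3; the other 32 of the 35 splits part duplicate arrays and called 0. Only 1 of the 35 splits reached 829, but duplicate arrays are not independent, and the 3 splits that keep them together are too few for a share under 0.05.

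For 1068 probes the log2 fold changes of P-5 and P-6 lay further apart than the spread between duplicate arrays gives (adjusted p under 0.05, limma), with opposite signs for 861 of them. Each line holds 1 sample per group, so whether the lines respond differently was not tested. MVK is among these probes, with -0.19 in P-5, -0.74 in P-6 and a gap of -0.56.

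Over 126 sets of 4 arrays, 1 array stood apart from the other 3 in 6. A chance rate of 1 in 20 holds for independent values, which duplicate arrays are not, so the 6 were not set against it. Dixon's ratio was 0.921 for the probes detected on the siRNA arrays, where an array of replicate 2 had 22404 against 22937 to 22983. It was 0.844 for INHBB, 0.937 for ECHS1 and 0.849 for TIGAR among siRNA arrays. Among control arrays it was 0.850 for MLXIPL and 0.861 for RIPK1.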

How the results depend on the processing

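The fits with a block on median-centred or series matrix values were chosen after seeing the data. In limma, 0 probes passed under every other normalization, filter, offset or prior run on averaged samples, with duplicateCorrelation on 8 arrays, with the replicate block on the 4 averaged samples, at an adjusted p under 0.1, and with a single array per replicate; over these settings 1464 to 4032 probes had an unadjusted p under 0.05. All 8 arrays as separate samples gave 829 probes, and with the replicate block 2986, since duplicate arrays then count as replicates. The replicate block gave 176 probes on median-centred and 74 on series matrix values; the cause was not tested. Leaving out 1 sample gave 0 to 11, the 11 without FASN siRNA replicate 1; the group left with 1 sample is then assumed to vary like the other. FASN was lower under all 20 settings, from -0.67 to -0.28, and -0.28 to -0.62 with 1 sample left out. It passed on 8 arrays, at -0.45 without the block (adjusted p = 0.0483) and -0.45 with the replicate block (adjusted p = 0.00953). The sign of each of the 60 other named genes held under every setting that tested it. These genes were picked on the same arrays for a small unadjusted p, so a steady sign says little about them. Of the 60, 37 passed on 8 arrays as samples and 56 with the replicate block there.

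The correlation between lines was 0.269 without background correction, 0.292 on series matrix values, 0.276 under median centring, 0.224 without a filter, 0.225 on first arrays and 0.184 on second arrays; the cause was not tested. The number of lists called fell from 7 to 4 on first arrays, 0 with an estimated correlation and 0 by fry. The 0 with an estimated correlation does not show what correlation alone does, since camera then has few degrees of freedom. Leaving out 1 sample gave 1 to 7, with 1 list without control replicate 1 and 2 without FASN siRNA replicate 2. Other settings gave 5 to 10, and the replicate block on averaged samples ended the call of the autophagy list and changed no other call. Of the lists not called, oxidative phosphorylation was called in 14 of 21 settings, immediate early genes in 5, ribosomal proteins in 3, and fatty acid oxidation and the TCA cycle in 2 each. These 5 and the 7 called lists kept their direction in camera under every setting run. Directions are given for these and for the synthesis of fatty acids and cholesterol, a choice made after seeing that lists near 0 often turn. Fatty acid synthesis, never called, turned upward with a sample left out (adjusted p = 0.996 without control replicate 1 and 0.913 without FASN siRNA replicate 1; 0.895 to 0.996 over the samples left out). Cholesterol synthesis turned downward under median centring (0.810; 0.788 with the replicate block) and on series matrix values (0.687; 0.587 with the replicate block), where the median of all probes moved to -0.13 and -0.10. Probes near background are limited by the signal over it: 10 of the 60 genes were not detected at p under 0.01 on all 8 arrays.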

Other observations

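The test of photoreceptor genes was chosen after the result was seen; the test of further ERK-responsive genes was set before their values were looked at, and the genes that prompted it were chosen after theirs were seen.

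Within the photoreceptor list, single genes stood on both sides of 0. The guanylate cyclase activators GUCA1A and GUCA1B had log2 fold changes of -0.88 and -0.69 (-0.95 at a second GUCA1B probe), phosducin (PDC) -0.76, the interphotoreceptor matrix gene IMPG2 -0.77, TULP1 -0.52, the cone opsin OPN1MW -0.47 (-0.33 at its other probe) and GUCA1C -0.38, while the rod channel subunit CNGB1 stood at 0.48 and 0.72 at 2 probes and UNC119 at 0.47 and 0.07. At an unadjusted p under 0.05 there were 10 lower and 2 higher of 37 genes, 32.4% against 7.97% of the 17623 other genes tested (one-sided Fisher's exact p = 1.9e-05, which treats genes as independent). That comparison restates the values that prompted it and excludes nothing. None of these genes passed over all genes or adjusted over the list alone.

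SPRY4 was 3.84-fold higher (log2 fold change 1.94, SE 0.358), with 1.88 in P-5 and 2.00 in P-6. ETV5 stood at 1.86, and its second probe was above background only in siRNA cells and at least 1.33-fold higher there, DUSP6 at 0.96 and SPRY2 at 0.89, and ETV4 was above background only in siRNA cells and at least 1.66-fold higher there. These are known feedback regulators and transcriptional targets of ERK signalling, and none passed the test (each adjusted p = 0.603). A higher output of the ERK pathway may link them. Of 7 further ERK-responsive genes, 3 were tested: EPHA2 stood at 0.71, EPHA4 at -0.04 and PHLDA1 at -0.34 (0.09 at its other probe). Their median lay at percentile 43.2 of matched random lists, which decides nothing with 3 genes that go both ways. SPRED2 (0.60) went with the pattern, and SPRED1 (0.10), EGR1 (0.28), IER3 (0.01), FOSL1 (-0.26) and SPRY1 (-0.23 and -0.10) less so or not.

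Among genes chosen after their values were seen, the cholesterol exporter ABCA1 stood at -0.34, its relative ABCG1 at -0.58, -0.69, -0.02 and 0.39 at 4 probes and the uncoupling protein UCP2 at -0.64, while ANGPTL4 stood at 0.41, 0.08 and -0.09 at 3 probes; all are on the list of LXR and PPAR targets, which was not called.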
